A study of Escherichia coli with 40 samples.

How the data were processed

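RNA of Escherichia coli was compared on 40 two-colour spotted arrays. Per the labels, channel 1 (Cy3) held RNA of the untreated culture in mid-log growth and channel 2 (Cy5) held RNA taken 5 min after the addition of S-nitrosoglutathione (GSNO) or, on the control arrays, of DPTA. The labels give total RNA, extraction with hot phenol and chloroform followed by a column, and direct incorporation of labelled dCTP. The 40 arrays came from 19 cultures in 10 groups of strain, medium and treatment. Each culture had 2 technical arrays, except the first metJ culture, which had 4.

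The authors deposited 1 normalised log ratio per spot and array, taken here as a log10 ratio. The deposited values are signed, symmetric about 0 and have array medians between -0.027 and 0.03, so they had been centred or normalised before deposit. Scanner, background correction, spot filter, normalisation, log base and direction are not given in the sources used here. Base 10 was read from the values: the SD between duplicate spots of a gene had a median of 0.0591 over the arrays, which is 14.6% in base 10 and would be 4.2% in base 2. The design had assumed log2 ratios. The values were therefore kept in deposited log units, folds are given for base 10, and the limit of 1 on the log2 scale became 0.301. The base changes no sign, p-value or count except where that limit is used.

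The direction of the ratio is likely treated over untreated. Its basis is the dyes in the labels and the positive values of hmp and ytfE, textbook nitric oxide inducible genes, in the wild type at 500 µM. No dye-swapped array is described, so a preference of a gene for 1 dye cannot be separated from a response within a group. Only the differences between groups remove it.

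Of 9340 spots, 8777 were assigned to 1 gene by the platform annotation, none to several, and 563 to none. The spots of a gene were averaged per array, which gave 4152 genes, of which 4147 matched the reference gene table used for current symbols. Of these genes, 4100 had 2 spots, 40 had 4 or 6 and 12 had 33 or 34. Each array was then centred on its median and the arrays of a culture were averaged, since they share its RNA. An array held 4368 to 8987 spots with a value.

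Testing used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on 1 value per culture. All 19 cultures entered 1 fit with a mean per group, since most groups had 2 cultures and 2 groups had 1. This left 9 residual degrees of freedom, and a lone culture was assumed to vary like the others. A gene was tested where at least 10 of the 19 cultures and all cultures compared had a value. Benjamini-Hochberg adjustment ran over the genes tested in a comparison, with a threshold of 0.05. The 20 comparisons were the mean of each group against 0 and 10 differences between groups. Errors are the standard errors of the fit. No comparison had 3 or more cultures on both sides, so counts over other splits of the samples were not made.

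There were 3 cultures whose log ratios ran opposite to the other GSNO cultures: the third wild-type culture at 100 µM, the second flhDC culture and the cysB culture. Their direction is not settled. Every comparison was therefore repeated without them (the fit of 16 cultures, 7 residual degrees of freedom) and with their sign turned. Both alternatives were added after seeing the data. Leaving cultures out by their values is a selection by outcome, so the fit of all 19 cultures stays the reference. For groups without an opposed culture these alternatives leave the means as they are and change the pooled spread. Its median residual SD was 0.073 over 19 cultures and 0.0576 over 16. Without the 3 cultures the set of genes tested changes slightly too, such as 3941 against 3958 genes at 500 µM.

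Before the data were examined, 27 gene lists were fixed from textbook knowledge: NsrR targets, NorR targets, MetJ regulon, CysB regulon, sulfonate use, flagella and chemotaxis, Fur iron uptake, Isc and Suf iron-sulfur assembly, SoxRS and OxyR regulons, heat shock, SOS response, branched-chain amino acids, arginine synthesis, aromatic amino acids, histidine, purine and pyrimidine synthesis, ribosomal proteins, FNR anaerobic respiration, aerobic respiration and ATP synthase, acid resistance, RpoS general stress, dipeptide and oligopeptide permeases, glutathione and thioredoxin, and copper and zinc stress. Lists with at least 3 members measured in all cultures of a fit (3143 genes for 19 cultures) were tested with camera at a preset correlation of 0.01. The same test with an estimated correlation and fry, which asks whether a list moves one way and compares it with no other genes, were alternatives. NorR targets had too few members and are given as genes. Members called are counted over all genes tested and adjusted over the list alone.

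Genes named were chosen by a rule fixed before the data were examined. It takes the 10 largest changes each way among called genes with 1 sign in all cultures (5 each way for single cultures), up to 4 called members per list, and a fixed set of nitric oxide, methionine, cysteine, iron-sulfur and flagellar genes with the disrupted genes. The rule was applied to the fit of all 19 cultures and again to the fit of 16. Per the labels both channels held RNA of the same strain, so the ratio of a disrupted gene does not check the label.

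The alternative settings fixed with the design were the values as deposited, quantile normalisation over the arrays, only genes with a value on all 40 arrays, all 40 arrays with the culture as a random block, eBayes with trend and robust, the culture number as a block, the limit on size, the spread of a group's own cultures (for the wild type at 500 and at 100 µM), and each culture left out in turn. The spread of a group's own cultures was also moderated by eBayes over the genes of that fit. The calculation was tested on simulated data drawn with the spread of these arrays. For the response at 500 µM over 3958 genes, 31.7% of genes changed by 0.15, 81.2% of those changed by 0.3 and 98.4% of those changed by 0.6 were recovered, with 6 unchanged genes called. For the difference from the DPTA arrays the shares were 7.94%, 53.1% and 95.3%, with 3 unchanged genes called. Simulated genes varied independently of each other, each with its own spread over the 19 cultures. The changed genes were drawn at random over all genes. Genes with opposite signs in the opposed cultures, such as hmp and metA, had a larger spread, so these shares overstate the recovery of such genes. The spots with no gene entered no comparison.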

Results

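Transcript ratios of Escherichia coli 5 min after the addition of S-nitrosoglutathione (GSNO), a nitrosated form of glutathione, were measured on 40 two-colour arrays from 19 cultures. Cells grew aerobically at 37 °C in MOPS medium with 0.5% glucose, and the series asks which regulators and pathways GSNO perturbs. The wild type had 2 cultures at 500 µM GSNO, 3 at 100 µM and 2 with the control compound DPTA. At 500 µM there were 2 cultures each of strains disrupted in nsrR, flhDC and metJ, 2 of the wild type with methionine, and 1 each of the wild type and of a cysB strain with cysteine. A dpp strain had 2 cultures at 100 µM. Each array gave values for 3128 to 4099 of 4152 genes.

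Values are mean log ratios in deposited units, likely treated over untreated, with the limma standard error of the fit of all 19 cultures unless the fit of 16 is named. The base is read as 10. Of the GSNO cultures, 3 ran opposite to the others: the third wild-type culture at 100 µM, the second flhDC culture and the cysB culture correlated across genes with the 500 µM wild-type mean at r = -0.529, -0.64 and -0.421. Genes are not independent replicates, so these r values describe the cultures only. Since the labels give these cultures the same dyes as the rest, their direction is not settled, and each comparison is also given without them (16 cultures) and with their sign turned.

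**Figure D1:**
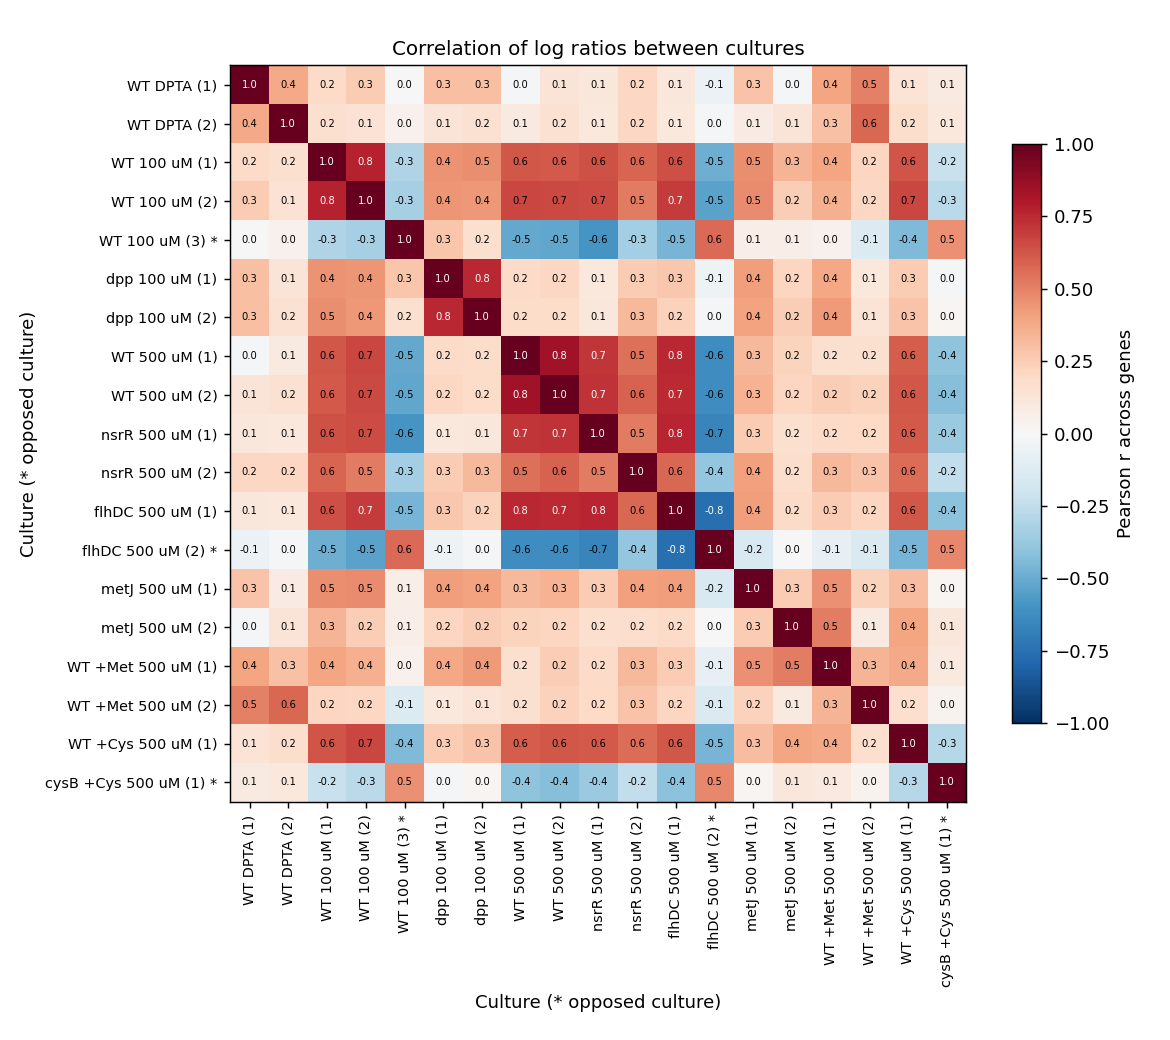
Pearson r across genes between the log ratios of each pair of the 19 cultures, with opposed cultures starred on both axes. The pair of wild-type cultures at 500 µM correlated at 0.84 and the pair of flhDC cultures at -0.75.

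At 500 µM GSNO in the wild type, genes of nitric oxide detoxification and methionine synthesis had positive ratios, and genes of sulfate assimilation, flagella and carbamoyl phosphate synthesis negative ones. The ratio of hmp, which encodes the nitric oxide dioxygenase flavohaemoglobin, was 1.08 ± 0.34 (SE, n = 2), or 11.9-fold. That of ytfE, an iron-sulfur repair gene, was 0.78 ± 0.33 and that of yeaR 0.67 ± 0.24. Among methionine genes, metA, which encodes the first enzyme of the pathway, had 1.10 ± 0.37 (12.7-fold). The activator gene metR had 1.27 ± 0.46, metF 0.94 ± 0.36 and metN of the methionine transporter 0.76 ± 0.28. Low values were found for carA, carbamoyl phosphate synthetase, at -1.11 ± 0.33, and for the ATP sulfurylase genes cysD and cysN at -0.97 ± 0.28 and -0.71 ± 0.30. The flagellar gene fliI stood at -0.67 ± 0.17 and rpsA, ribosomal protein S1, at -0.67 ± 0.27. None of these 12 genes passed the test in the fit of all 19 cultures, where hmp had an adjusted p of 0.174, metA 0.186, ytfE 0.252 and carA 0.161. All 12 passed in the fit of this group's 2 cultures alone, an alternative fixed with the design, and again in the fit of 16 cultures. With the group's own spread hmp (adjusted p = 3.14e-06), metA (1.56e-08) and ytfE (2.08e-07) rose and carA (2.45e-08) and cysD (1.22e-05) fell. With 2 cultures these p-values lean on the spread that eBayes pooled over all genes, not on the replicates of each gene alone. The signs of hmp and ytfE were used in reading the direction of the ratio, so their rise is no separate result.

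The fit of all 19 cultures called 11 of 3958 genes at 500 µM, 7 higher and 4 lower, with 706 at an unadjusted p under 0.05. The 4 that fell were flhD, a subunit of the flagellar master regulator, at -0.55 ± 0.10 (adjusted p = 0.0361), ycaI at -0.46 ± 0.08, tdcR at -0.24 ± 0.04 and mrcA at -0.23 ± 0.04. Those that rose included ycgY at 0.44 ± 0.07, uxaA at 0.36 ± 0.06 and the dicarboxylate carrier gene dcuB at 0.32 ± 0.05. The count was 986 (462 higher, 524 lower) with the spread of the group's own cultures, 769 (376 and 393) in the fit of 16 cultures and 502 (247 and 255) with the sign turned. It was 0 with the values as deposited, 0 without culture 1 and 0 without culture 2. From the fit of 16 cultures it was 156 without culture 1 and 468 without culture 2.

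By list at 500 µM, the MetJ regulon, genes under the methionine repressor, had a median of 0.55 with all 13 measured members positive. Over 19 cultures 0 of them were called over all genes and 6 rose adjusted over the list alone, and over 16 cultures 10 rose. Camera gave an adjusted p of 0.000653 and 1.24e-08, but 0.628 and 0.268 with an estimated correlation. The flagella and chemotaxis list had a median of -0.19, with 36 of 48 members negative. There 1 member fell over all genes, 26 fell and 7 rose adjusted over the list alone, and over 16 cultures 30 fell and 5 rose. Camera's adjusted p was 4.04e-06, but 0.628 with an estimated correlation. For fliA, the flagellar sigma factor, the ratio was 0.08 ± 0.05. NsrR targets, under the nitric oxide sensing repressor, had a median of 0.08, with 8 of 8 positive (camera adjusted p = 0.0319, but 0.628 with an estimated correlation). Over 16 cultures 3 of the 8 rose, namely hmp, ytfE and yeaR, while ygbA stood at 0.05 ± 0.05 and hcp at 0.06 ± 0.06. norV of the NorR targets, the nitric oxide reductase, had 0.08 ± 0.06 with an adjusted p of 0.478, and norW was not measured in both cultures.

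Several biosynthetic lists also had medians below 0 at 500 µM with camera p-values past the threshold in the fit of all 19 cultures. The ribosomal proteins had a median of -0.13 (camera adjusted p = 0.000653), aerobic respiration and ATP synthase -0.09 (0.00283), and Isc iron-sulfur assembly -0.14 (0.0086). Histidine synthesis had -0.12 (0.008), pyrimidine synthesis -0.13 (0.0128), the CysB regulon -0.21 (0.0158), purine synthesis -0.09 (0.0206), the peptide permeases -0.09 (0.0289), branched-chain amino acids -0.08 (0.0382) and aromatic amino acids -0.10 (0.0465). With an estimated correlation the adjusted p was 0.628 for each of these 10 lists. No member of them was called in that fit over all genes, and adjusted over the list alone 2 peptide permease genes fell. These medians are against 0 and so keep any dye preference. On the DPTA arrays, without GSNO, the ribosomal proteins had a median of -0.08, with 49 of 53 members negative. Over 16 cultures 23 of 48 ribosomal protein genes and 9 of 18 CysB genes fell and 1 of each rose. There 5 of 8 Isc genes fell, among them the co-chaperone gene hscB at -0.38 ± 0.05, whereas iscR stood at -0.02 ± 0.04. The remaining lists, namely sulfonate use, Fur iron uptake, Suf assembly, SoxRS, OxyR, heat shock, SOS response, arginine synthesis, FNR anaerobic respiration, acid resistance, RpoS, glutathione and thioredoxin, and copper and zinc stress, had medians between -0.15 and 0.06. Their camera adjusted p-values lay between 0.153 and 0.996, with 1 heat shock and 1 copper gene risen adjusted over the list alone. soxS had 0.18 ± 0.08, oxyR 0.04 ± 0.06 and frmA, the GSNO and formaldehyde dehydrogenase gene, 0.06 ± 0.05, and none was called in the fit of all 19 cultures.

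**Figure D2:**
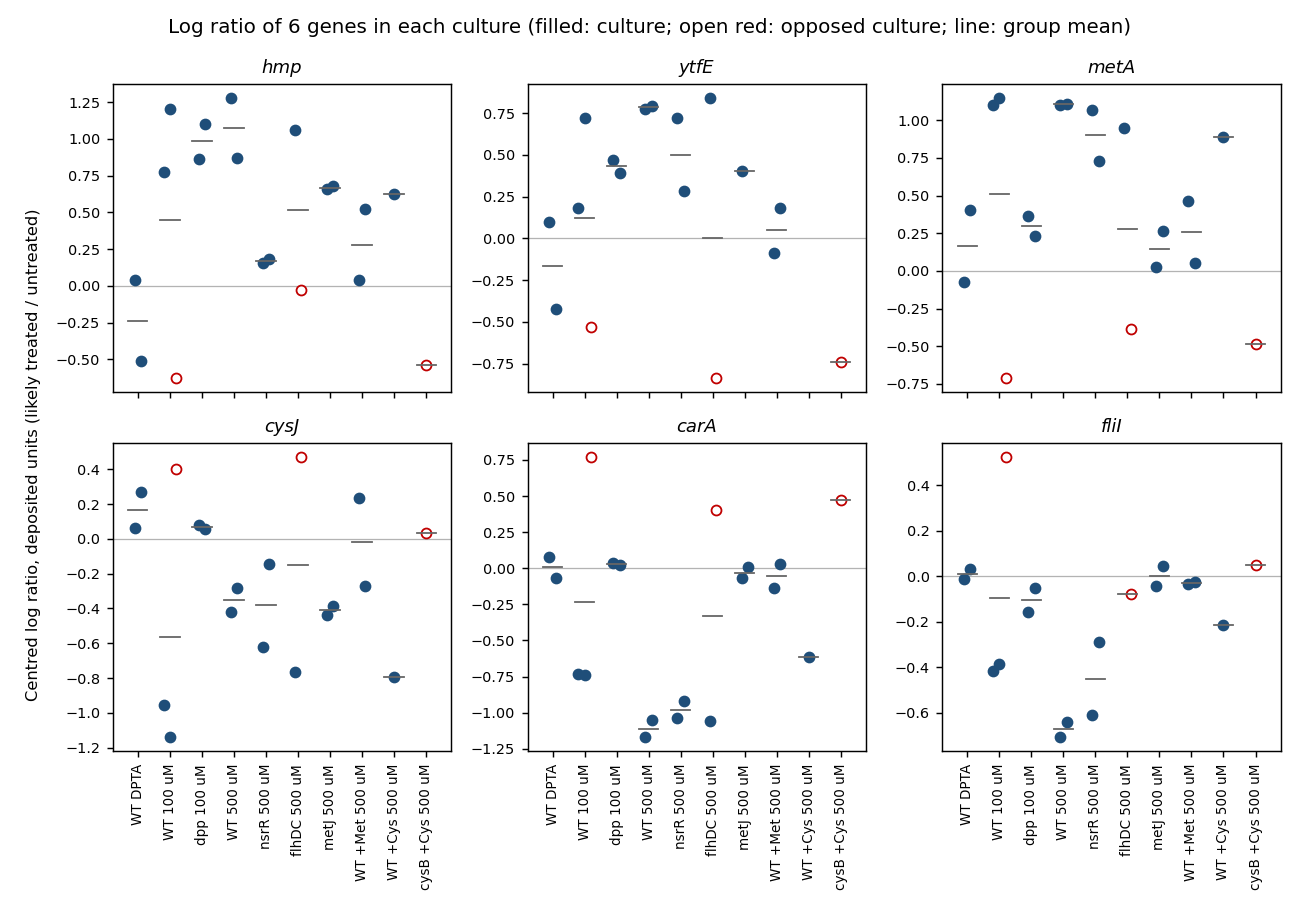
Mean log ratio of each culture (points, deposited log units on the vertical axis) for 6 genes, with the groups on the horizontal axis, group means as lines and opposed cultures as open red points. hmp stood at 1.28 and 0.871 in the 500 µM wild type and at 0.159 and 0.18 in the nsrR strain.

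At 100 µM GSNO in the wild type, the third culture ran opposite. The fit of all 19 cultures could thus hardly call genes that changed sign with that culture, and those it called changed little. Those that fell included ydhR at -0.32 ± 0.04 (adjusted p = 0.00374, n = 3), the exoribonuclease gene rnb at -0.30 ± 0.04, and the adenine salvage gene apt at -0.34 ± 0.10. Others were the ribosomal protein genes rpsT at -0.32 ± 0.08 and rpmF at -0.28 ± 0.07, the superoxide dismutase gene sodA at -0.25 ± 0.04 and the cytochrome bo oxidase genes cyoA at -0.24 ± 0.05 and cyoB at -0.20 ± 0.06. Those that rose included csrC, a small RNA that binds the regulator CsrA, at 0.27 ± 0.04, and gcvR at 0.28 ± 0.08. For hmp, metA and cysJ, a sulfite reductase gene, the third culture had the opposite sign, and their means were 0.45 ± 0.27, 0.51 ± 0.30 and -0.57 ± 0.26, with no call. Over 16 cultures, with the other 2 cultures of the group, hmp rose by 0.98 ± 0.14 (adjusted p = 0.000147), metA by 1.12 ± 0.11 (1.96e-05) and metR by 1.16 ± 0.13. In that fit cysJ stood at -1.05 ± 0.11, cysH at -0.81 ± 0.10 and carA at -0.74 ± 0.05, all called.

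Of 3879 genes tested at 100 µM, 1526 (39.3%) had 1 sign in all 3 cultures. The fit called 397, 131 higher and 266 lower, and 393 of the called genes had 1 sign. Of 392 of these with a control value, 76.8% had the same sign in the DPTA arrays, where their median was 0.0327 in the direction of the call against 0.149 at 100 µM, where the genes were chosen. Over 19 cultures 6 of 50 ribosomal protein genes (camera adjusted p = 0.000635), 7 of 31 aerobic respiration genes (0.00952) and 4 of 47 flagellar genes (0.00952) fell, and adjusted over the list alone 6, 9 and 3. With an estimated correlation the adjusted p was 0.919 for all 3 lists. On the DPTA arrays 49 of 53 ribosomal protein genes were negative too. Over 16 cultures 13 of 14 MetJ genes rose (median 0.58), 13 of 17 CysB genes fell and 1 rose (median -0.37), and 38 of 50 ribosomal protein genes fell and 1 rose. Camera's adjusted p for the MetJ list was 0.21 over 19 cultures and 5.72e-07 over 16, but 0.365 over 16 with an estimated correlation. The count was 1509 (656 higher, 853 lower) in the fit of 16 cultures and 836 (345 and 491) with the sign turned. It was 0 with quantile normalisation, 0 with the spread of the group's own cultures and 5 with the limit on size. It was 16 without culture 1, 62 without culture 2 and 1001 without culture 3, and from the fit of 16 cultures 775 without culture 2.

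Between the doses, the fit of all 19 cultures called 0 of 3785 genes, with 488 at an unadjusted p under 0.05. Over 16 cultures carA was lower at 500 than at 100 µM, by a difference of -0.37 ± 0.07 (adjusted p = 0.0267), as was flhD at -0.35 ± 0.09, and cysJ was higher, at 0.70 ± 0.15 (0.0366). The differences of hmp, 0.09 ± 0.19, and metA, -0.02 ± 0.15, were not called, which does not show that the doses acted alike. That fit called 127 genes (94 higher, 33 lower). It called 1 without culture 1 at 500 µM, 18 without culture 2 at 500 µM and 29 without culture 2 at 100 µM. Turning the sign gave 5 genes.

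With the control compound DPTA the nitric oxide and methionine genes had no call. hmp stood at -0.24 ± 0.34 (n = 2), with 0.04 and -0.51 in the individual cultures, ytfE at -0.16 ± 0.33, metA at 0.17 ± 0.37 and norV at -0.09 ± 0.06. The tests by limma gave 0 of 4059 genes in the fits of 19 and of 16 cultures and with the sign turned, 162 at an unadjusted p under 0.05, and 16 with quantile normalisation. Ribosomal proteins had a median of -0.08 with DPTA (camera adjusted p = 2.62e-09, but 0.999 with an estimated correlation). MetJ genes had a median of 0.09 with DPTA, with 13 of 14 positive, and CysB genes 0.09, with 14 of 18 positive. Camera's adjusted p was 0.517 and 0.363 over 19 cultures and 0.107 and 0.00698 over 16. With an estimated correlation over 16 it was 0.907 for both. The dose of DPTA is not given in the labels, so the compounds were not compared at a matched dose.

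The difference between GSNO and DPTA removes a dye preference common to both. At 500 µM the fit of all 19 cultures called 0 of 3931 genes, with 334 at an unadjusted p under 0.05, and the difference of hmp was 1.31 ± 0.47 (adjusted p = 0.53). Over 16 cultures 178 genes were higher and 127 lower. There hmp (difference 1.31 ± 0.19, adjusted p = 0.00113) and metA (0.94 ± 0.15, 0.00223) were higher with GSNO, and carA (-1.11 ± 0.07, 9.5e-07), cysD (-1.12 ± 0.14) and fliI (-0.68 ± 0.08) were lower. Without culture 1 at 500 µM that count was 64, and it was 78 and 130 without DPTA culture 1 and 2. At 100 µM the counts were 0 of 3853 over 19 cultures, with 371 at an unadjusted p under 0.05, and 578 (225 higher, 353 lower) over 16, with differences of 1.22 ± 0.19 for hmp, 0.96 ± 0.15 for metA and -1.22 ± 0.15 for cysJ. Without culture 2 at 100 µM it was 225, and without DPTA culture 1 and 2 it was 171 and 149. Turning the sign gave 165 genes at 500 µM and 144 at 100 µM.

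In the nsrR strain, which lacks the repressor of hmp and ytfE, the methionine and carA changes were present and that of hmp was small. hmp stood at 0.17 ± 0.34 (n = 2; 1.48-fold), ytfE at 0.50 ± 0.33, metA at 0.90 ± 0.37 and metN at 0.73 ± 0.28. carA was at -0.98 ± 0.33, cysD at -0.49 ± 0.28 and soxS, the superoxide response regulator gene, at 0.32 ± 0.08. None was called over 19 cultures. Over the 16 cultures metA (adjusted p = 0.000201), metN, ytfE (0.026) and soxS (0.000656) rose and carA (5.4e-08) and cysD fell, while hmp had an adjusted p of 0.415. Against the wild type at 500 µM, hmp differed by -0.91 ± 0.47 and ytfE by -0.28 ± 0.46, and neither was called, with an adjusted p for hmp of 1 over 19 cultures and of 0.0988 over 16. The NsrR targets had a median difference of -0.18 (camera adjusted p = 0.00794 and 0.000202, but 0.973 and 0.105 with an estimated correlation), and adjusted over the list alone 0 of 8 were lower over 19 cultures and 2 over 16. MetJ genes had a median of 0.46 in this strain, with 11 of 14 risen in the fit of 16 cultures (camera adjusted p = 2.19e-09, but 0.336 with an estimated correlation). limma called 0 of 3783 genes in the response over 19 cultures, with 517 at an unadjusted p under 0.05. It called 581 over 16 (83 without culture 1 and 1015 without culture 2) and 274 with the sign turned. For the difference it called 0 of 3695 in each of the 3 fits, with 142 at an unadjusted p under 0.05 over 19 cultures. From the fit of 16 cultures it called 33 and 57 genes without nsrR culture 1 and 2 and 5 without wild-type culture 2.

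The flhDC strain, which lacks the master regulator of flagellar genes, had cultures of opposite sign. Culture 1 gave 0.95 for metA, 1.06 for hmp and -1.06 for carA, and culture 2 gave -0.39, -0.03 and 0.40. The fit of all 19 cultures called 0 of 4009 genes, with 83 at an unadjusted p under 0.05. The fit of 16 cultures rests on culture 1, and in it 512 genes were called (234 higher, 278 lower), and with the sign turned 508 (216 and 292). Over 16 cultures metA (0.95 ± 0.15, adjusted p = 0.00273) and hmp (1.06 ± 0.19, 0.00448) rose and carA (-1.06 ± 0.07, 1.84e-06) fell. Flagellar genes differed from the wild type at 500 µM by a median of 0.16 over 19 cultures and 0.18 over 16 (camera adjusted p = 1.49e-06 and 1.06e-17). With an estimated correlation the adjusted p was 0.687 and 0.0535, and it was 0.0144 with the sign turned. Adjusted over the list alone 2 of 44 members were higher over 19 cultures, and 20 of 45 were higher and 2 lower over 16. The genes called as higher over 16 cultures were flgI (0.71 ± 0.12), flgE (0.56 ± 0.08), flgF (0.53 ± 0.08), cheW (0.50 ± 0.09), yecR (0.42 ± 0.06), hsdR (0.42 ± 0.07) and flhD, a gene disrupted in this strain. In flhDC culture 1, flgI, flgE, flgF, cheW and flhD stood at 0.07, 0.095, -0.02, 0.02 and 0.07. In the 500 µM wild type they stood at -0.64, -0.47, -0.55, -0.48 and -0.55. Their differences thus come from the low values of the wild type. yecR stood at 0.30 in flhDC culture 1 and at -0.125 in the wild type. hsdR stood at -0.03 and 0.66 in flhDC culture 1 and 2 and at -0.45 in the wild type. For this difference limma called 0 of 3884 genes over 19 cultures, with 155 at an unadjusted p under 0.05, 7 over 16 (0 without wild-type culture 1 and 12 without culture 2) and 17 with the sign turned.

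In the metJ strain, which lacks the methionine repressor, methionine genes stood near 0 after GSNO, as did carA, fliI and flhD. metA had 0.14 ± 0.37 (n = 2) and metF 0.06 ± 0.36. hmp had 0.67 ± 0.34 (4.65-fold) and cysD -0.34 ± 0.28, and none of these was called in any of the 3 fits. leuA, of leucine synthesis, stood at 0.24 ± 0.06 and was the gene called over 16 cultures (adjusted p = 0.0388), not over 19 (0.752). It was not called in the fit of 16 cultures without culture 1 or without culture 2. The branched-chain amino acid list had a median of 0.09, with 3 of 15 members risen and 1 fallen adjusted over the list alone. Its camera adjusted p was 0.000118 over 19 cultures, but 0.642 with an estimated correlation, and 0.0177 with an estimated correlation over 16. CysB genes had a median of -0.22 (0.000185, but 0.884 with an estimated correlation). Against the wild type at 500 µM, MetJ genes differed by a median of -0.54 (camera adjusted p = 0.0006, but 0.559 with an estimated correlation). Branched-chain genes differed by 0.17 (1.11e-05, but 0.409 with an estimated correlation over 19 cultures, and 0.0272 over 16). Over 16 cultures metA (-0.96 ± 0.15, adjusted p = 0.0023) and metF (-0.88 ± 0.16) were lower in the strain, and leuB (0.40 ± 0.06), hscB (0.43 ± 0.07), fliI (0.67 ± 0.08) and carA (1.08 ± 0.07, 1.33e-06) higher. The difference of hmp was -0.41 ± 0.19 and not called. In metJ culture 1 and 2, carA stood at -0.07 and 0.01, fliI at -0.04 and 0.05 and flhD at 0.03 and 0.02. Log ratios had an SD of 0.055 and 0.086 in these cultures, against 0.158 and 0.120 in the 500 µM wild type. Of these, metJ culture 1 averaged 4 arrays, which can lower its SD, and the others 2. The lower response is thus not particular to methionine genes, but not all genes had it. Of 17 CysB genes 15 were negative. cysJ stood at -0.438 and -0.384, against -0.42 and -0.28 in the 500 µM wild type. cysD, however, stood at -0.349 and -0.324, against -1.21 and -0.734. A weaker signal on these arrays was not tested. Counts by limma were 0 of 3654 for the response over 19 cultures, with 164 at an unadjusted p under 0.05, and 1 over 16 and with the sign turned. For the difference they were 0 of 3598, with 194 at an unadjusted p under 0.05, 201 over 16 (51 without wild-type culture 1, 108 and 52 without metJ culture 1 and 2) and 131 with the sign turned.

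With methionine in the medium, the wild type at 500 µM had metA at 0.26 ± 0.37 (n = 2), hmp at 0.28 ± 0.34 and the methionine synthase gene metE at 0.24 ± 0.14, and none was called. The cultures differed, with 0.05 and 0.47 for metA, 0.52 and 0.04 for hmp and -0.16 and 0.64 for metE in culture 1 and 2. Over 16 cultures 4 of 31 genes of aerobic respiration fell, with nuoG at -0.25 ± 0.04 (adjusted p = 0.0154) and the succinate dehydrogenase genes sdhC at -0.24 ± 0.05 and sdhA at -0.23 ± 0.04. entF, of enterobactin synthesis, rose by 0.21 ± 0.03. The respiration list had a median of -0.07, and 1 of 31 members fell adjusted over the list alone over 19 cultures. Its camera adjusted p was 0.00119, but 0.773 with an estimated correlation, and with an estimated correlation 0.0441 over 16 and 0.337 with the sign turned. Across genes culture 2 correlated with the DPTA cultures at 0.506 and 0.576, with culture 1 at 0.343 and with the 500 µM wild-type cultures at 0.157 and 0.233. Culture 1 correlated with the DPTA cultures at 0.396 and 0.291 and with the 500 µM wild-type cultures at 0.164 and 0.245. Compared with the 500 µM wild type without methionine, metA differed by -0.84 ± 0.15, ytfE by -0.74 ± 0.19, hmp by -0.80 ± 0.19, cysD by 0.99 ± 0.14 and carA by 1.06 ± 0.07 in the fit of 16 cultures. All 5 were called there (adjusted p = 0.00484 for metA and 0.024 for hmp), and none over 19. The median difference of the MetJ list was -0.47 (camera adjusted p = 0.0456, but 0.893 with an estimated correlation). Flagellar genes differed by a median of 0.15 and Isc genes by 0.18 (0.00646 for both lists, but 0.893 with an estimated correlation). limma called 0 of 3975 genes for the response over 19 cultures, with 296 at an unadjusted p under 0.05. It called 14 over 16 (2 without culture 2 and 9 without culture 1), 25 with quantile normalisation and 0 with the sign turned. For the difference it called 0 of 3872, with 329 at an unadjusted p under 0.05, 250 over 16 (51 without wild-type culture 1, 115 and 86 without methionine culture 1 and 2) and 145 with the sign turned.

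The dpp strain, disrupted in the dipeptide permease genes, had high hmp and ytfE ratios at 100 µM GSNO, while single methionine and cysteine genes were called as different from the wild type over 16 cultures and not over 19. hmp had 0.98 ± 0.34 (n = 2; 9.65-fold), ytfE 0.43 ± 0.33, metA 0.30 ± 0.37, cysD 0.31 ± 0.28, cysJ 0.07 ± 0.32 and carA 0.03 ± 0.33. The copper exporter gene copA had -0.30 ± 0.05 and sdhC -0.26 ± 0.09. No gene of 3903 was called in the fit of all 19 cultures, with 837 at an unadjusted p under 0.05. Over 16 cultures 493 were called (213 higher, 280 lower), of which hmp (adjusted p = 0.00537) and ytfE (0.0486) rose and copA (0.00226) and sdhC (0.012) fell. Without culture 1 that count was 1, without culture 2 it was 0, and with the sign turned it was 0. Quantile normalisation gave 165 genes over 19 cultures. The copper and zinc list had a median of -0.16, with 3 of 10 fallen adjusted over the list alone (camera adjusted p = 0.0371, but 0.476 with an estimated correlation, and 0.0125 by fry). Flagellar genes had a median of -0.10, with 39 of 49 negative (camera adjusted p = 0.00311, but 0.926 with an estimated correlation). Over 16 cultures 10 of them fell and 1 rose.

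Against the wild type at 100 µM, CysB genes were higher in the dpp strain by a median of 0.31 over 19 cultures and 0.52 over 16 (camera adjusted p = 3.13e-05 and 6.81e-12, but 0.922 and 0.268 with an estimated correlation). MetJ genes differed by -0.12 and -0.55 (0.35 and 6.86e-09, but 0.922 and 0.268 with an estimated correlation). Over 16 cultures 11 of 17 CysB genes were higher, such as cysJ by 1.12 ± 0.15 (adjusted p = 0.0024) and cysD by 0.95 ± 0.14. carA was higher by 0.77 ± 0.07, and 6 of 14 MetJ genes were lower, such as metA by -0.83 ± 0.15 (0.00959). Other lists differed over 16 cultures too. There 13 of 50 ribosomal protein genes were higher (camera adjusted p = 1.76e-10, but 0.268 with an estimated correlation). Of 12 arginine synthesis genes 6 were higher (0.000814, but 0.268), and of 48 flagellar genes 9 were higher and 1 lower. The differences of hmp, 0.00 ± 0.19, and ytfE, -0.02 ± 0.19, were not called. limma called 0 of 3756 genes over 19 cultures, with 144 at an unadjusted p under 0.05, and 168 with the sign turned. It called 261 over 16 (158 higher, 103 lower), and the count was 41 and 14 without dpp culture 1 and 2 and 81 without wild-type culture 2.

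With cysteine in the medium, the wild type had 1 culture, assumed to vary like the others and with no replicate check. Over 19 cultures 4 of 3830 genes were called, with 292 at an unadjusted p under 0.05: rcnR, a nickel and cobalt responsive repressor gene, at 0.55 ± 0.05 (adjusted p = 0.000442, n = 1), ybbY at 0.54 ± 0.07, hybG at -0.50 ± 0.05 and fau at -0.35 ± 0.05. metB at 1.03 ± 0.18 (adjusted p = 0.00791), metA at 0.89 ± 0.15, cysJ at -0.80 ± 0.15, cysD at -0.59 ± 0.14, carA at -0.62 ± 0.07 and norV at 0.19 ± 0.05 were called over 16 cultures, where the count was 158, and hmp at 0.62 ± 0.19 was not. It was 78 with the sign turned, and with quantile normalisation 1 gene was higher and 2 lower. MetJ genes had a median of 0.59 (camera adjusted p = 0.0019, but 0.844 with an estimated correlation) and CysB genes -0.41 (4.56e-05, but 0.844 with an estimated correlation). Against the wild type without cysteine, rcnR was higher by 0.45 ± 0.07 (adjusted p = 0.0313) and hybG lower by -0.48 ± 0.06 (0.0129). These were 2 of 3704 genes called, with 190 at an unadjusted p under 0.05, and neither was called without wild-type culture 1 or without culture 2. Over 16 cultures 26 differed, among them carA (0.49 ± 0.08) but not metA (-0.21 ± 0.19) or hmp, with 3 called without wild-type culture 1, and 0 were called with the sign turned.

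The cysB strain, which lacks the activator of cysteine synthesis genes, had 1 culture, and it ran opposite to the others. Values as deposited were -0.76 ± 0.08 for norV (adjusted p = 0.00334, n = 1), -0.62 ± 0.06 for norW, -0.40 ± 0.07 for iscR, the iron-sulfur cluster regulator gene, and 0.35 ± 0.04 for ppiA, the 4 of 4065 genes called, with 50 at an unadjusted p under 0.05. Turned, each value has the opposite sign and 9 genes were called, so the size of these changes is given without a direction. hmp, ytfE and metA had -0.54 ± 0.47, -0.74 ± 0.46 and -0.49 ± 0.53, and cysJ 0.04 ± 0.45. Ribosomal proteins had a median of 0.08 as deposited (camera adjusted p = 0.000104, but 0.887 with an estimated correlation). Against the wild type with cysteine, 5 of 3795 genes were called as deposited, with 164 at an unadjusted p under 0.05: norV (-0.95 ± 0.12), norW (-0.65 ± 0.09), rcnR (-0.61 ± 0.08), hybG (0.44 ± 0.07) and ppiA (0.41 ± 0.06). This set 1 culture against 1 with the spread of other groups, and rcnR and hybG stood at 0.55 and -0.50 in the cysteine culture and at -0.06 and -0.07 in the cysB culture. Likewise the CysB list had a median of -0.41 in the cysteine culture and of 0.0002 in the cysB culture. Its difference thus comes from the cysteine culture and hardly depends on turning. The MetJ list had medians of 0.59 and, as deposited, -0.13 in these cultures. CysB genes differed by a median of 0.43 as deposited and 0.40 turned, and MetJ genes by -0.66 and -0.37 (camera adjusted p = 0.00134 and 0.000468 as deposited, but 0.778 for both with an estimated correlation). On turning, rcnR and hybG kept their signs, norV and norW became 0.57 and 0.58, and 4 genes were called.

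Per the labels, both channels of an array held RNA of 1 strain, so the ratio of a disrupted gene in its own strain checks no label. These ratios were -0.14 ± 0.05 for nsrR, -0.01 ± 0.10 for flhD, 0.04 ± 0.21 for metJ, -0.03 ± 0.04 for dppA and 0.00 ± 0.06 for cysB.

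**Figure D3:**
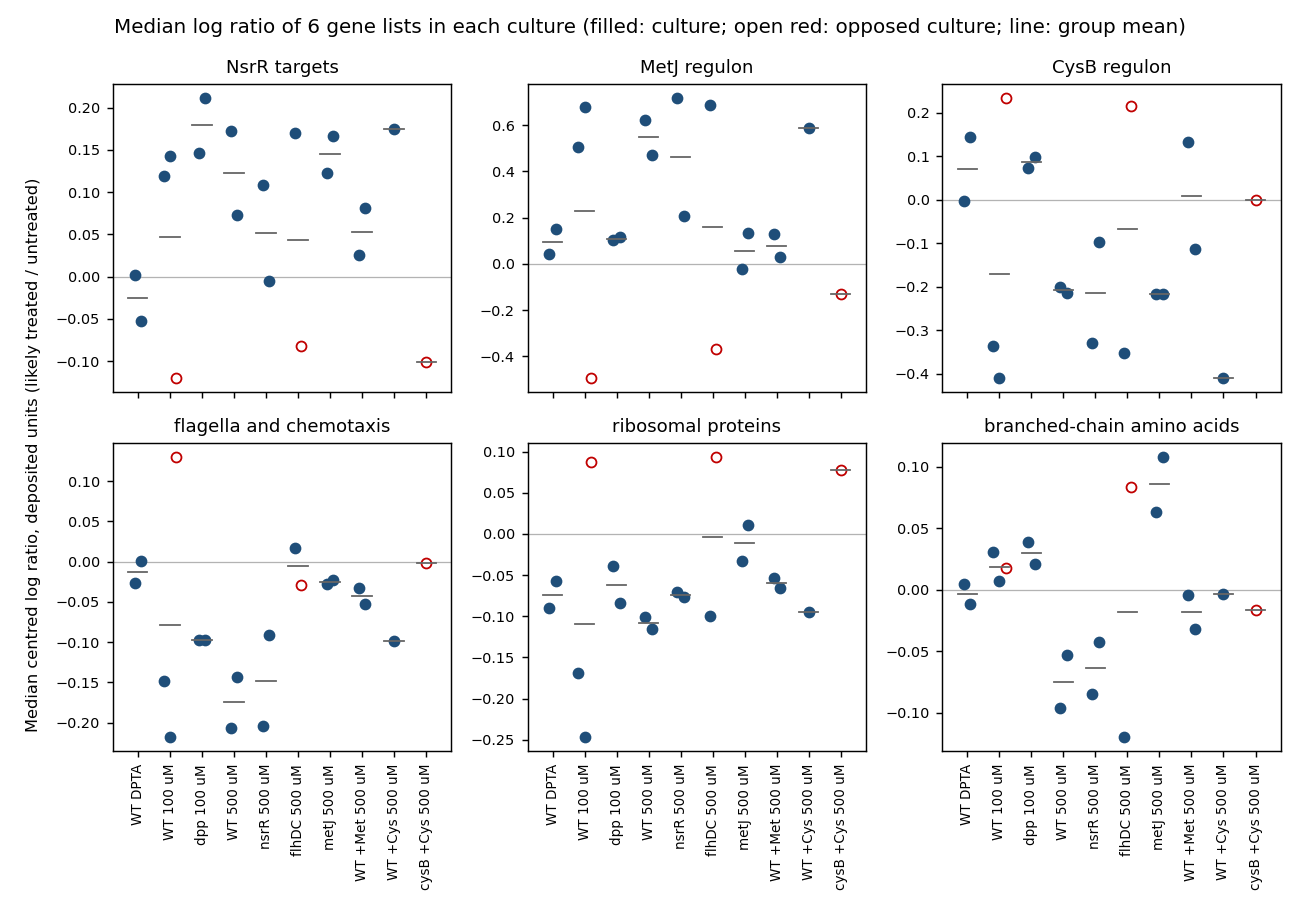
Median log ratio of 6 gene lists in each culture (points, deposited log units on the vertical axis), with the groups on the horizontal axis, group means as lines and opposed cultures as open red points. The MetJ regulon had medians of 0.622 and 0.472 in the 500 µM wild-type cultures and of 0.0288 and 0.129 with methionine.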

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

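The correlation test of noise below, the test of a response to GSNO and both tests on the dpp strain were chosen after their results were seen, as was the fit of 16 cultures in which most differences were found. The test on dye bias and those on exchanged signs were written before their results, though after the cultures' correlations were known.

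The third wild-type culture at 100 µM, the second flhDC culture and the cysB culture stood far from the others, with log ratios of the opposite sign. Noise or a failed hybridisation would put their correlations with the 500 µM wild type near 0, and they were -0.529, -0.64 and -0.421, where an earlier test, the percent of the 986 genes with the opposite sign (74.2, 85.5 and 70.9), had left 2 of the 3 undecided. A sign turned when the ratios were computed was predicted to leave only noise in 1 part of the values. This is the part that kept its sign between an opposed culture and its partners. In the 100 µM and flhDC groups these parts had a partial correlation of 0.35 over 3744 genes, given the 500 µM response, where noise gives about 0. The prediction failed, but it cannot decide on a turned sign. Cultures of unequal response would leave a response common to both groups and unlike that at 500 µM. For instance, cysJ stood at -0.956, -1.14 and 0.402 at 100 µM and at -0.766 and 0.471 in flhDC, against -0.42 and -0.28 at 500 µM. Treated and untreated RNA, or their dyes, exchanged at the bench may account for the pattern and needs such a positive value (0.35), though a dye bias would also be present in the DPTA arrays, with which these parts correlated at 0.239 and 0.142 only, and any other component common to both groups would give 0.35 too. No biological explanation was tested, and for the cysB culture its genotype stays open.

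Of the 397 genes called at 100 µM, 393 had 1 sign in all 3 cultures although the third culture ran opposite overall. A dye preference of the 393 genes is a candidate explanation, since 76.8% had the same sign in the DPTA arrays, which held no GSNO, narrowly past the bound of 75%. The share over all genes tested was not computed, so it is not known whether this share is particular to them. Sizes bear on a response to GSNO only outside the wild type at 100 µM, where the genes were chosen: the median in the direction of the call was above that of both DPTA cultures (0.0316 and 0.0315) in 11 of 14 GSNO cultures, at 0.118 and 0.0982 in the dpp cultures at 100 µM and at 0.00125 to 0.0615 in those at 500 µM. The 3 that were not above were opposed flhDC culture 2, the opposed cysB culture and methionine culture 2, so neither explanation is excluded. The same sign was found in 96.9% and 92.3% of the genes in the dpp cultures, and at 500 µM in 50.5% (flhDC culture 2) to 89.6% (metJ culture 1).

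In the fit of 16 cultures, the median of MetJ genes was 0.58 in the wild type at 100 µM and 0.13 in the dpp strain, and that of CysB genes -0.37 and 0.07. A weaker signal on the dpp arrays would have shrunk all genes alike. Over the 4 pairs of a dpp and a wild-type culture the medians of the called MetJ genes were 15.3% to 24.5% of the wild type. Those of CysB genes were -23.1% to -9.29%, against 38.1% to 52.5% for the other called genes. This cannot decide on it, since 376 of the 393 genes with 1 sign in all 3 cultures were also called in this fit. A dye preference, a candidate for them, need not shrink with the signal and would raise the percent of the other genes. With DPTA the MetJ and CysB medians were both 0.09, so the dpp medians lay near those of the control. Against wild-type culture 1 and 2 alone, hmp stood at 127% and 82.3% and ytfE at 240% and 60.1%. A weaker signal stays open, and the slope of the dpp values on the wild-type values over the 1488 genes called at 100 µM was 0.289. Loss of the permease and any other difference between the sets of cultures cannot be told apart, since each strain had 1 set, and the median MetJ difference was -0.38 against 1 wild-type culture and -0.567 against the other.

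The differences between groups found by limma in the fit of 16 cultures were 305 genes for 500 µM GSNO against DPTA, 578 for 100 µM against DPTA, 127 between the doses, 7 for the flhDC strain, 201 for the metJ strain, 250 for methionine, 261 for the dpp strain and 26 for cysteine. In the fit of all 19 cultures cysteine differed in 2 genes and the cysB strain in 5, but with 1 culture against 2 and 1 against 1 these rest on the spread of other groups. These counts concern the groups as labelled and carry no direction where an opposed culture enters.

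Among 563 spots without a gene name, 368 had values in both groups and 2 had log ratios of 1 sign in both cultures at 500 µM, there over 0.301 in size and beyond both control cultures. They stood at -0.428 and -0.363, and at -0.433 and -0.335, in the 2 cultures, while the highest absolute control value was 0.127 and 0.11. Their spot numbers, 1079 and 1080, are adjacent. Since most genes had 2 spots, they may be duplicates of 1 feature.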

How the results depend on the processing

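The fits without the 3 opposed cultures, with their sign turned and with crossed culture numbers, and the culture-by-culture omissions inside the fit of 16 cultures, were added after the data were seen. The others were fixed before. The 3 opposed cultures limit the calls: with them 86 of 520 list and comparison pairs passed camera, against 148 of 468 without them and 166 with their sign turned. An estimated correlation gave 0, 3 and 5 of these pairs, and fry 3, 123 and 122. Groups of 1 to 3 cultures, 1 dye orientation and a log base read from the values limit every comparison, and no signal over background was at hand to judge dim spots. The cause of the changes below was not tested, except that a limit on size leaves fewer calls by construction.

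With the values as deposited, 500 µM GSNO gave 0 genes and the dpp response 2. Quantile normalisation gave 5 genes at 500 µM, 0 at 100 µM, 16 with DPTA, 14 for metJ, 25 with methionine, 165 for dpp, and, for the differences, 1 for metJ, 1 for cysteine (lower) and 3 for cysB; the cysteine response then had 1 higher and 2 lower, against 2 and 2. Genes measured on all 40 arrays gave 3 at 500 µM, 69 for dpp, and 0 for the cysteine and cysB responses and their differences. Taking 40 arrays with a random block (correlation 0.542) gave 270 at 500 µM, 717 at 100 µM, 58 for nsrR, 1 for metJ, 8 with methionine, 139 for dpp and 14 with cysteine. Its differences were 21 for 500 µM against DPTA, 36 between doses, 3 for flhDC, 4 for metJ, 21 for methionine and 4 for cysteine.

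Trend and robust moderation gave 7 genes at 500 µM, 249 at 100 µM, 1 for the nsrR difference and 1 for the cysteine difference. An absolute log2 ratio of at least 1 left 5 at 500 µM and 5 at 100 µM. The spread of a group's own cultures gave 986 at 500 µM and 0 at 100 µM.

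The labels give no pairing by culture number, and with 2 numbers shared the values do not settle one: deviations of same-numbered cultures correlated across genes at 0.251 for nsrR and 0.33 for flhDC with the 500 µM wild type, at -0.152, -0.124 and -0.111 for the comparisons with DPTA and between doses, and between -0.0799 and 0.00272 for dpp, metJ and methionine. With the number as a replicate block, 500 µM gave 0 genes, 100 µM 716, 500 and 100 µM against DPTA 12 and 30, and the flhDC, metJ, methionine and cysteine differences 9, 6, 12 and 1. Crossed numbers gave 7 genes for 500 µM against DPTA.

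Leaving out 1 culture at a time, with a lone culture assumed to vary like the others, gave between 0 and 0 genes at 500 µM and for the cysteine difference. The range was 16 to 1001 at 100 µM, 0 to 26 for nsrR, 0 to 28 for 100 µM against DPTA, and 0 to 1 for the doses and for the nsrR and flhDC differences. It was 0 for the other comparisons with a culture to leave out. The cysteine response and both cysB comparisons rest on lone cultures, and none could be left out there.

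Without the 3 opposed cultures the responses counted 769 genes at 500 µM, 1509 at 100 µM, 581 for nsrR, 512 for flhDC, 1 for metJ, 14 with methionine, 493 for dpp and 158 with cysteine. The differences counted 305, 578, 127, 7, 201, 250, 261 and 26. With the sign turned, the responses counted 502, 836, 274, 508, 1 for metJ, 78 with cysteine and 9 for cysB, and the differences 165, 144, 5, 17, 131, 145, 168 and, for cysteine, 0. The cysB strain has no value without its culture. With the sign turned norV, norW, iscR and ppiA reversed to 0.76, 0.62, 0.40 and -0.35 in the cysB response, and norV, norW and ppiA to 0.57, 0.58 and -0.29 in its difference.

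For the single genes named, the settings fixed before left 1152 values on the same side of the threshold, moved 75 past it and 86 below it, and reversed 0. The added fits left 149, moved 153 past it and 7 below it, and reversed 7.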

Other observations

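The fit of 16 cultures and the correlations of single cultures in this part were chosen after the result was seen; the values over 19 cultures were planned.

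At 500 µM GSNO these single genes were called in the fit of 16 cultures and not over 19. The cold shock gene cspB stood at -0.85 ± 0.11 (SE, n = 2) in the fit of 16 cultures (adjusted p = 0.00018, against 0.226 over 19 cultures), and purF, which starts purine synthesis, at -0.40 ± 0.07 (0.000802, against 0.254). dps, of DNA protection in starvation, rose there by 0.36 ± 0.06 (0.000852, against 0.222), and the succinate dehydrogenase gene sdhC fell, with -0.20 ± 0.05 (0.00841, against 0.274). In the dpp strain at 100 µM, cspG stood at -0.51 ± 0.11 (adjusted p = 0.0178, against 0.171) and the iron-sulfur gene iscS at 0.24 ± 0.04 (0.012, against 0.103) in the same fits. yehD stood at 0.32 ± 0.04 in the dpp strain and at 0.29 ± 0.04 with methionine, called over 16 cultures (0.00537 and 0.0154) and not over 19 (0.053 and 0.1).

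The second DPTA culture and the second methionine culture correlated across genes at 0.576, and metE stood at 0.59 and 0.64 in them but at 0.09 and -0.16 in the first culture of each group. Technical arrays of a culture correlated at 0.429 to 0.844 across genes. The lowest value was that of the second flhDC culture.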
